A study of Homo sapiens with 4 samples.

How the data were processed

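RNA from RKO cells was hybridised to 4 one-colour Agilent expression arrays. RKO is an established human colorectal carcinoma line with an activating BRAF mutation. The cells had been treated for 24 h with 0.1% DMSO, with 1 µM tretinoin, with 10 µM encorafenib plus 10 µM binimetinib, or with all 3 drugs, per the labels. Tretinoin is all-trans retinoic acid, the ligand of the retinoic acid receptors. Encorafenib inhibits BRAF and binimetinib inhibits MEK, the kinase downstream of BRAF. Each group had 1 array, and the labels placed every sample in its group. Total RNA was extracted on silica columns, and Cy3-labelled cRNA was made from 100 ng of it, per the labels' protocols.

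The scanner files held spot intensity values that the authors deposited as Agilent Feature Extraction 10.7.3.1 wrote them, per the file headers. The processed signal in these files is an intensity after local background subtraction, and the header names the human build hg19. All 4 arrays lay on 1 slide and came from 1 scan, at positions 1 to 4. Position on the slide and treatment could therefore not be told apart, and no slide block could be fitted.

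The authors also deposited a table of log2 values for 32021 probes, of which 31984 were among the non-control probes used here. Its columns were matched to the arrays by their names. Over 31707 singly spotted probes, the difference between columns equalled the difference of log2 processed signal plus a constant per array, within 0.0001 for 100% of probes. The constants relative to DMSO were -0.04 for tretinoin, -0.0037 for the inhibitors and 0.03 for the 3 drugs. Each probe was centred on its median over the 4 arrays, and the direction was that of the labels. The column medians were 0.03 for DMSO, 0.01 for tretinoin, -0.01 for the inhibitors and -0.03 for the 3 drugs. The header of that deposited table names filters on detection flags and on a raw signal of at least 10. In the scanner files, 100% of its non-control probes had such a signal on at least 1 array and 84.0% on all 4. What set the constant of each array stays unknown.

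For each array, log2 of the processed signal was taken and the array's 75th percentile over non-control spots was subtracted. Spots marked as non-uniform or as population outliers by the scanner software were left out, between 48 and 82 per array. No spot was saturated. Spots whose local background was marked as a population outlier were kept. They numbered 127 with DMSO and 334 with tretinoin, but 2607 with the inhibitors and 3548 with the 3 drugs. The higher numbers go with both inhibitor treatment and slide position, which cannot be told apart. The 10 spots of each of 300 replicated probes were averaged, which left 58201 probes. Accessions were looked up in a RefSeq table of GRCh38.p14 genes, used for names only, so that no coordinates are given. A symbol was found for 38314 probes, 34982 of them by accession and the rest from the deposited table. The other 19887 probes stayed unnamed. The named probes covered 26791 genes, 8506 of them with several probes. A gene was read from 1 probe, the one well above background on the most arrays, with ties going to the higher mean signal.

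A gene was measured on an array where its probe was well above background by the scanner software's own test. Where only 1 of the arrays compared met this, the fold was a lower bound. It set the bright array against the lowest signal well above background on the other array, or against the dim probe's own value if that was higher. These floors lay between -4.79 and -4.61 on the log2 scale. Genes not well above background on either array got no fold.

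With 1 array per group there was no test, no p-value and no error across cultures. Genes at least 2-fold higher or lower were counted as a description of these arrays. Each of 26 gene lists of 634 genes in all, 631 of them with a probe, was described by the median log2 difference of its measured genes. That median was ranked among 10000 random lists of the same size drawn from 20 bins of mean signal. The lists covered retinoic acid response, retinoid metabolism enzymes, HOX genes, ERK pathway output, receptor tyrosine kinases and ligands, G1/S and DNA replication, and G2/M and mitosis. They also covered CDK inhibitors and quiescence, p53 targets, the BCL2 family, the integrated stress response, heat shock and protein folding, the interferon response, inflammatory cytokines and NF-kB, and WNT targets. The rest were intestinal differentiation, epithelial-mesenchymal transition, cholesterol synthesis and uptake, glycolysis and hypoxia, YAP targets, autophagy and lysosome, ribosome biogenesis, PI3K and FOXO feedback, reference genes, leukocyte markers, and fibroblast and endothelial markers.

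The genes named in the text followed a rule. For each comparison it took the 12 highest and 12 lowest differences among genes measured on both arrays. It added the 4 largest bounds in each direction and up to 4 members of each list with the largest difference, or more where the list's description needed them. Names of uncharacterised loci were left out, and a few genes that the rule selects are not reported here. Among the highest and lowest measured differences, a gene was skipped where another of its measured probes differed in sign or by more than 1 log2 unit. Bounds and list members were not checked for this. The lists, the rule and the alternatives were fixed before the data were examined, except where the text says otherwise.

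The comparisons made were 4 differences: tretinoin against DMSO, the 3 drugs against the inhibitors, the inhibitors against DMSO, and the 3 drugs against tretinoin. Both tretinoin differences share no array, and neither do both inhibitor differences. The difference of the tretinoin effects subtracts the first from the second, over the 15877 genes measured on all 4 arrays.

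Precision was limited by the number of arrays. The only error the arrays themselves gave was that between spots of one probe. Its median SD was 0.044 on the log2 scale, so that a difference between single spots carried a technical error of 0.062. That figure holds for bright probes, because 1050 of the 1100 pairs of probe and array lay above the array's 75th percentile. The root mean square SD was 0.095 over 35 pairs at log2 signals from -2 to 0, 0.22 over 11 pairs from -4 to -2, and 0.33 over 4 pairs below -4. Adding only such noise, with the SD of the gene's own signal range, to unchanged genes gave 20.9 genes with an apparent 2-fold difference between tretinoin and DMSO, as a mean of 20 simulations. The simulation covered only genes measured on both arrays, whereas the 2-fold counts for this comparison include 52 higher and 30 lower bounds. Spot error leaves out culture, labelling and array.

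The procedure was tested on simulated data for tretinoin against DMSO, with 200 genes altered by a known fold and the same noise by signal range around the DMSO levels. These altered genes were drawn only from genes bright on the DMSO array, and their calls of well above background were held fixed. Their recovery therefore does not bear on dim genes. Of genes altered 3-fold, 33 of 33 raised and 34 of 34 lowered ones were counted as at least 2-fold different, and so were all 33 raised and 33 lowered 6-fold. None of the 34 raised or 33 lowered by 1.5-fold was counted, but 37 of 16923 unaltered genes were. For 50 genes dim on the DMSO array, the median bound was 4.03 where the true value was 6.03. Of 20 unaltered lists, also drawn from bright genes, 19 lay between the 2.5 and 97.5 percentiles.

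The alternatives fixed beforehand were normexp background correction with an offset of 50, quantile normalization, scaling to the median of probes measured on all 4 arrays, the authors' table, a stricter and no filter on dim probes, the mean over probes, single probes, 1.5-fold and 3-fold thresholds, and unmatched random lists. The scanner files as read here carried no mean signal column, so normexp was run on the median spot signal. Scaling to the spike-in controls and leaving out spots near local defects were added after the data were seen. A spot counted as near a defect with at least 3 non-uniform spots within 4 rows and columns on its array. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1, were used.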

Results

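Gene expression was measured on 4 one-colour arrays of RKO cells, a human colorectal carcinoma line whose BRAF kinase is constitutively active. The cells had received DMSO, tretinoin, the BRAF inhibitor encorafenib with the MEK inhibitor binimetinib (called the inhibitors from here on), or tretinoin with both inhibitors, for 24 h. Each group had 1 array, so no difference given here has a replicate check. Between 29829 and 31052 of the 60901 non-control spots per array were well above background, with 75th percentiles of the signal between 273 and 284. Spots with an outlying local background were more frequent with the inhibitors (2607) and the 3 drugs (3548) than with DMSO (127) and tretinoin (334). Repeat spots of one probe gave a technical error of 0.062 for a log2 difference, but 1050 of the 1100 pairs of probe and array behind it were brighter than the 75th percentile. The 4 faintest pairs had an error of 0.47, and the error between cultures was not measured. The study asked whether tretinoin alters other genes when BRAF and MEK are inhibited, so the tretinoin difference was taken without and with the inhibitors.

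Some retinoic acid response genes were higher with tretinoin alone than with DMSO. DHRS3, which reduces retinaldehyde to retinol and is a known retinoic acid target, was at least 231-fold higher than with DMSO, where it was not well above background. Of the 24 measured genes of the retinoic acid response list, 15 were positive and 9 negative, 5 at least 2-fold higher and 0 at least 2-fold lower. Besides DHRS3 these were STRA6, a receptor for retinol-binding protein, at least 4.05-fold higher, the transglutaminase TGM2 at 3.57-fold, the nuclear receptor corepressor NRIP1 at 2.87-fold, and CYP26B1, which clears retinoic acid, at 2.59-fold. The list's median difference of 0.17 on the log2 scale lay at the 99.99 percentile of random lists matched on expression (0.11 with genes above background on both arrays only). Enzymes of retinoid metabolism had a median of -0.02, at the 54.2 percentile, with 0 of 11 at least 2-fold different.

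Across all genes, 232 were at least 2-fold higher with tretinoin and 57 at least 2-fold lower, of 17404 measured. Among the highest differences measured on both arrays were those of SMAD3, a transcription factor of TGF-beta signalling (log2 difference 3.94, 15.3-fold), the cyclic nucleotide phosphodiesterase PDE2A (3.78), the keratin KRT80 (3.78) and the glucose-responsive transcription factor MLXIPL (3.25). The histone genes H2BC26 (3.08) and H2AC25 (2.84), SUN3 (3.06), the receptor GPRC5A (2.61), the HMG-box factor TOX2 (2.59), IGFBP6 (2.32) and the gonadotropin subunit CGB3 (2.23) followed. C11orf86 (at least 3.54), SYN1 (at least 11.3-fold) and UCN2 (at least 3.37) were well above background with tretinoin and not with DMSO. On the lower side stood the matrix metalloproteinases MMP3 (3.48-fold lower) and MMP1 (3.12-fold lower), OSTF1 (-1.51), the cAMP phosphodiesterase PDE4B (-1.28), the LC3 family gene MAP1LC3C (-1.25) and LY96 (-1.23). GDNF (at least -1.94), MAP2 (at least -1.91) and BARHL2 (at least -1.79) were not well above background with tretinoin. The large bound of RIC3 (-7.31) on this side comes from a spot of the DMSO array with 20 non-uniform spots within 4 rows and columns. Leaving out spots near such defects gave 232 higher and 48 lower genes, and normexp background correction gave 100 and 10.

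Of the other lists, ERK pathway output had a mixed difference with tretinoin alone, with a median of 0.21 at the 100 percentile (0.08 under normexp background correction). Of 31 genes 20 were positive and 11 negative. EGR3 (1.06) was at least 2-fold higher, and none was at least 2-fold lower, DUSP5 (-0.82) and DUSP6 (-0.35) being the lowest. HOX genes had a median of 0.10 (99.03 percentile, and 0.07 at the 96.4 percentile with the mean over probes) with 0 of 29 at least 2-fold different. The PI3K and FOXO feedback list had a median of 0.21 (99.99 percentile, and 0.12 under normexp background correction) and YAP targets 0.18 (99.94 percentile) with CCN2 at 1.16. Inflammatory cytokines and NF-kB genes had 0.13 (98.97 percentile, and 0.03 at the 86.5 percentile under normexp background correction). Interferon response genes had a median of -0.23 at the 0 percentile, with 19 of 25 negative and none at least 2-fold lower. In the p53 list, with a median of 0.03 (73.2 percentile), GDF15, a secreted stress-induced factor, was 4.50-fold higher and SPATA18 2-fold higher (1.04). Scaling to the spike-in controls lowers every median in this comparison by 0.081, leaving ERK pathway output at 0.13 and HOX genes at 0.02.

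**Figure D1:**
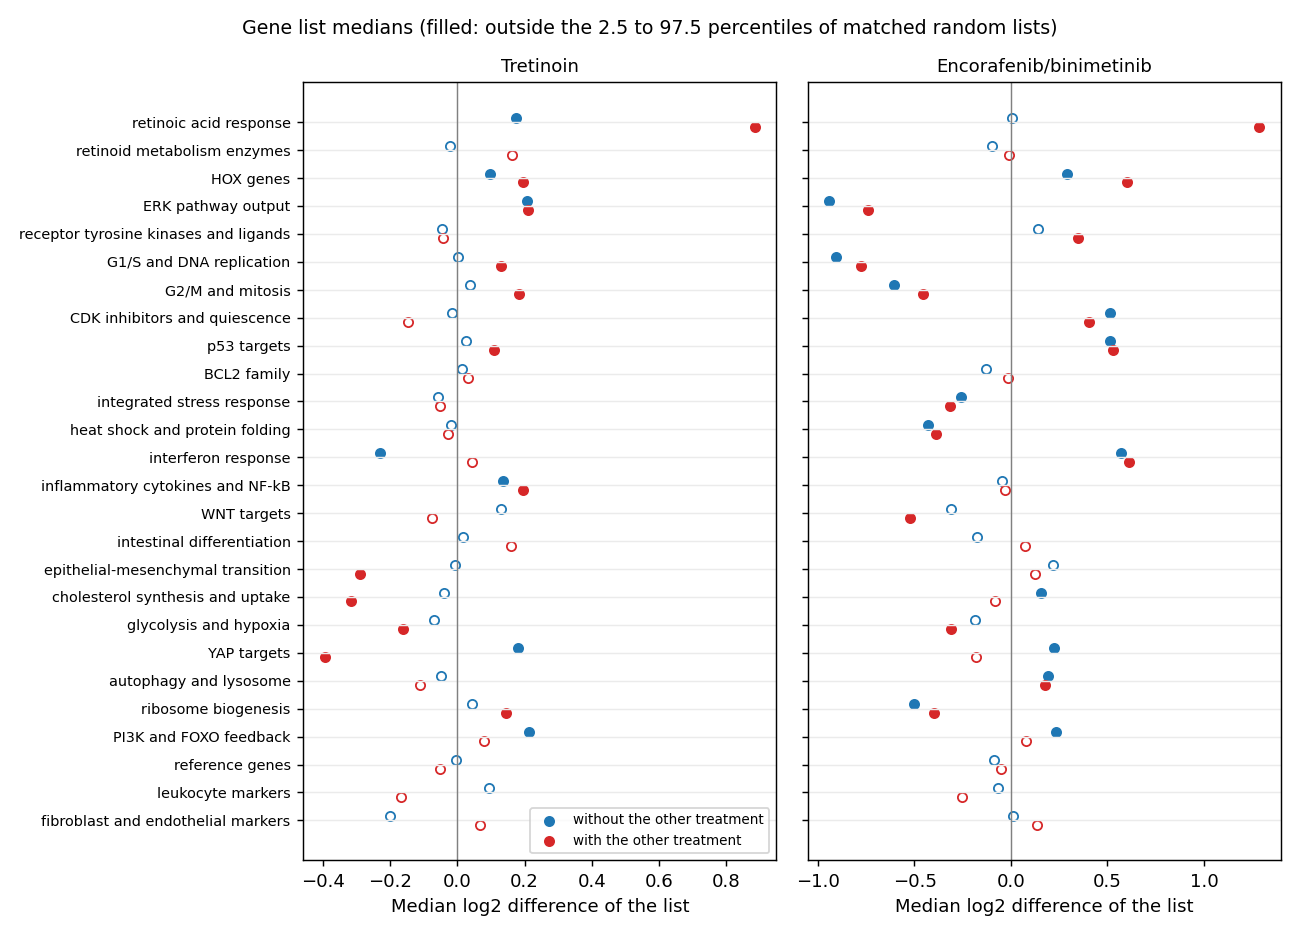
Median log2 difference of each of the 26 gene lists. The left panel shows tretinoin minus its control without (blue) and with (red) the inhibitors, and the right panel shows the inhibitors minus their control without (blue) and with (red) tretinoin. Filled circles lie outside the central 95% of 10000 matched random lists. The retinoic acid response list sits at 0.17 and 0.88 on the left.

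With the inhibitors present, more of the retinoic acid response genes were at least 2-fold higher with tretinoin. Of 27 measured genes 12 were at least 2-fold higher and 1, SMAD7, 4.01-fold lower, with a median of 0.88 at the 100 percentile (0.46 under normexp background correction). DHRS3 was 387-fold higher, and STRA6 at least 161-fold, CYP26A1, the main retinoic acid hydroxylase, at least 37.3-fold and CYP26B1 at least 10.2-fold. For DHRS3 this does not show a larger tretinoin difference, because the 231-fold without the inhibitors is only a lower bound. Its log2 signals were -6.10 with DMSO and 3.08 with tretinoin, against -3.23 with the inhibitors and 5.37 with the 3 drugs. The retinoic acid binding protein CRABP2 was 12.8-fold higher with the inhibitors against 1.10-fold without them. The receptor RARG was 4.81-fold against 1.86-fold higher, and RARRES1 had differences of 2.35 and -0.43. TGM2 went the other way, with 0.59 against 1.84. Retinoid metabolism enzymes had a median of 0.16 (96.0 percentile, and 0.09 under normexp background correction), with RDH12 at least 9.35-fold higher and RDH5 at 1.26.

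Some HOX genes, which pattern the body axis and respond to retinoic acid in embryos, were also higher with tretinoin in the presence of the inhibitors. HOXA4 was 8.82-fold higher, HOXA5 7.07-fold and HOXA3 3.53-fold, followed by HOXA6 (1.51) and HOXB3 (1.33). These 5 of 31 measured HOX genes were at least 2-fold higher and 0 lower, and the list's median of 0.20 lay at the 100 percentile (0.13 under normexp background correction). HOXB9 (-0.66) and HOXC10 (-0.53) were on the other side. Without the inhibitors the tretinoin differences of HOXA4 and HOXA5 were 0.34 and 0.33.

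**Figure D2:**
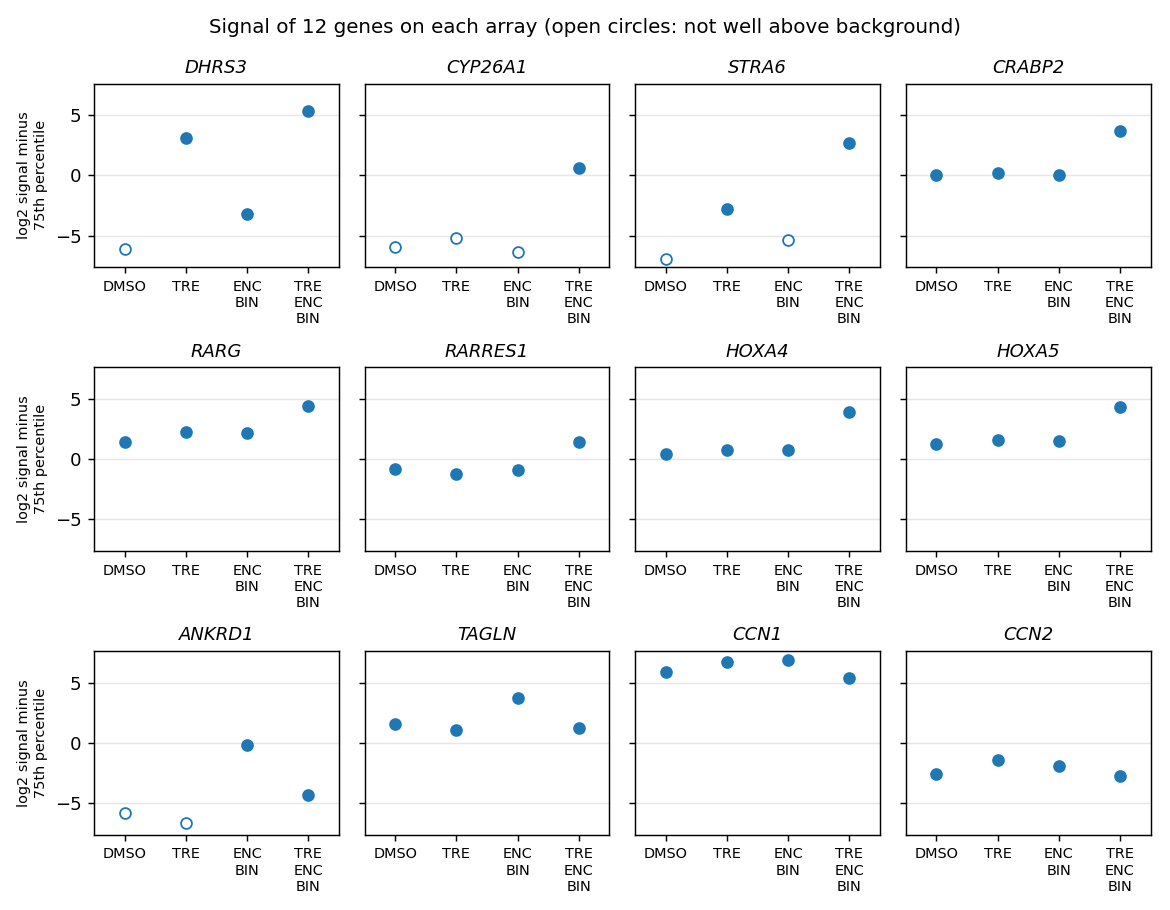
Signal of 12 genes on each of the 4 arrays (log2 signal minus the array's 75th percentile on the y axis, array on the x axis). Each circle is 1 array, and open circles are not well above background. CRABP2, HOXA4 and HOXA5 lie close together on the first 3 arrays and higher on the array with all drugs, while TAGLN is highest with the inhibitors alone (3.74).

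In all, 386 genes were at least 2-fold higher and 168 at least 2-fold lower with tretinoin on top of the inhibitors, of 17311 measured. The receptor tyrosine phosphatase PTPRH was 155-fold higher, TOX2 26.7-fold, the granzyme inhibitor SERPINB9 15.0-fold, the lipoprotein lipase inhibitor ANGPTL4 14.5-fold and the tight junction gene CLDN4 11.7-fold. S100P (3.82), H2AC25 (3.78), ZNF488 (3.73), the protease PRSS22 (3.72), the immune checkpoint gene VSIR (3.70) and BCL3 (3.44) were also among the highest. C11orf86 (at least 7.04) and the prostaglandin E synthase PTGES (at least 6.65) were not well above background with the inhibitors alone. On the lower side, ANKRD1, a YAP target, was 17.1-fold lower, FILIP1L differed by -3.32, the actin-binding TAGLN by -2.47, smooth muscle actin ACTG2 by -2.19 and calponin CNN1 by at least -1.72. PDE4B (-2.31), LURAP1L (-2.27), KLF9 (-2.27), ANXA1 (-1.99) and RGMB (-1.99) followed, with MAP2 (at least -4.09), CACNA1A (at least -1.89) and TMEM125 (at least -1.76). USP22 (-3.997) rests on a spot of the inhibitor array with 4 non-uniform spots within 4 rows and columns. Normexp background correction gave 219 higher and 51 lower genes.

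YAP targets had a median of -0.39 at the 0 percentile in this comparison, with 3 of 16 at least 2-fold lower (ANKRD1, CCN1 at -1.54 and ARHGEF17 at -1.03) and 13 negative. Cholesterol synthesis and uptake genes had a median of -0.32 (0 percentile), with 23 of 24 negative and none at least 2-fold lower. The largest was LSS at -0.94. The median of epithelial-mesenchymal transition genes was -0.29 (0.22 percentile, and -0.12 under normexp background correction), and that of glycolysis and hypoxia genes -0.16 (0.95 percentile), although CA9, a carbonic anhydrase, was at least 13.8-fold higher. ERK pathway output had a median of 0.21 (100 percentile), with UPP1 (2.83), FOSB (2.45), EPHA2 (1.42) and IER2 (1.13) higher and KLF6 (-1.58) and DUSP6 (-1.31) lower. Inflammatory cytokines and NF-kB genes had a median of 0.19 (99.5 percentile) with IL11 8.36-fold higher. In the interferon list, with a median of 0.04 (92.4 percentile), the transcription factor IRF1 was 5.69-fold higher against 1.18-fold without the inhibitors, and RSAD2 was at least 1.88. Small positive medians were found for G1/S and DNA replication genes (0.13, 99.99 percentile, with E2F2 at 1.53), G2/M and mitosis genes (0.18, 100 percentile), ribosome biogenesis genes (0.14, 100 percentile) and p53 targets (0.11, 99.6 percentile, with GDF15 at 2.51).

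Both tretinoin differences, which share no array, had 58 genes at least 2-fold higher in common, where independent lists would share 3.89 of 16703. They had 5 genes at least 2-fold lower in common, where 0.33 would be shared. Those 5 were PDE4B, MAP2, TMEM125, TMEM88 and the locus LOC105374051, a full list given after the values were seen. Shared higher genes included DHRS3, SMAD3, TOX2, GDF15 and the histone genes H2AC25 and H2BC26. One gene, MAP1LC3C, was at least 2-fold lower without the inhibitors (-1.25) and at least 2-fold higher with them (2.12), where independent lists would share 0.78. The opposite turn was found for 0 genes, against 1.65. Across the 15877 genes measured on all arrays, which are not independent replicates, the differences had a Pearson r of 0.37 and a Spearman rho of 0.33. Normexp background correction left 32 shared higher genes and 1 shared lower gene.

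**Figure D3:**
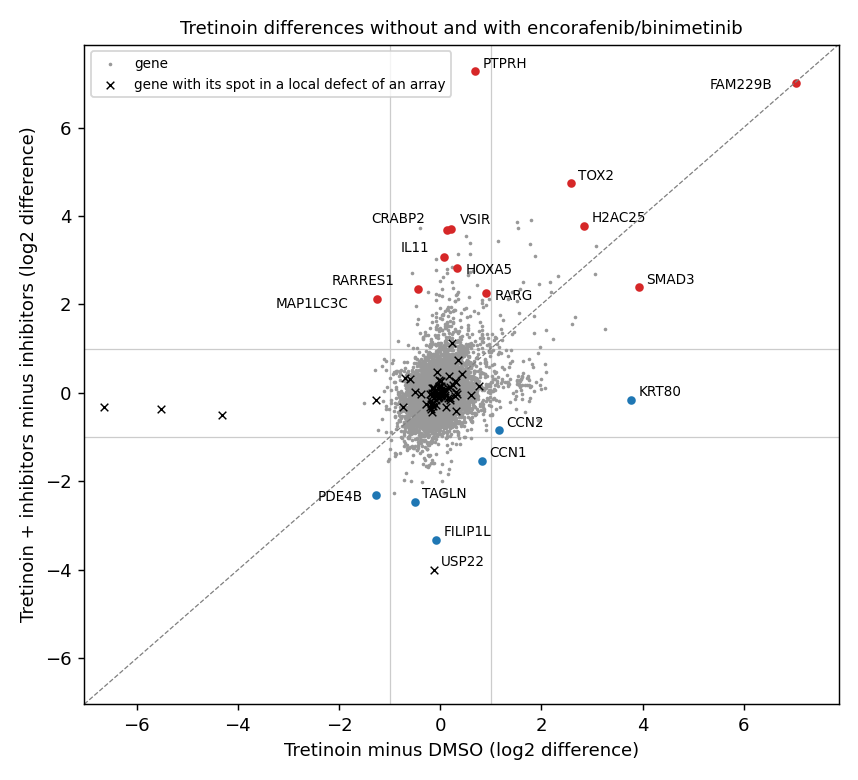
Log2 difference of tretinoin minus DMSO (x axis) against tretinoin with inhibitors minus inhibitors (y axis) for the 15877 genes measured on all 4 arrays. Grey lines mark 2-fold differences, the dashed line marks equal differences, and crosses are genes whose spot lies in a local defect of an array. PTPRH lies at 0.69 and 7.27, KRT80 at 3.78 and -0.15. FAM229B is labelled although the naming rule skipped it, because its probes disagreed.

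Subtracting one tretinoin difference from the other left 258 genes at least 2-fold higher with the inhibitors than without and 190 at least 2-fold lower. Spot noise alone would give 93.9 such genes, because 4 arrays enter the value. PTPRH (6.59), ZNF488 (4.14), VSIR (3.49), MAP1LC3C (3.37), PLK2 (3.12), CLDN4 (3.04), the cytokine gene IL11 (2.98), PTPRJ (2.81), HOXA4 (2.80), RARRES1 (2.78), KMT5C (2.67) and SH2B1 (2.61) were among the highest. PLK2 signals with DMSO (-4.43) and tretinoin (-4.52) lay near the floors of -4.76 and -4.66, and PTPRH was at -4.30 with DMSO. KRT80 (-3.93), FILIP1L (-3.25), RNF150 (-2.56), CCN1 (-2.36), KLF9 (-2.35), PWRN1 (-2.10), ANXA1 (-2.02), CCN2 (-2.01), the CDK inhibitor CDKN2B (-1.98), TAGLN (-1.96) and CAMKK1 (-1.90) were among the lowest, with USP22 (-3.87) from the defect already named. The retinoic acid response list had a median of 0.38 at the 100 percentile, with 16 of 20 genes positive, 5 at least 2-fold higher and 2 at least 2-fold lower (SMAD7 at -1.64 and TGM2 at -1.24). HOX genes had a median of 0.04 (86.2 percentile, 0.12 under normexp background correction and 0.10 when scaled to the spike-in controls), with 5 of 29 at least 2-fold higher. YAP targets had a median of -0.62 (0 percentile), cholesterol genes -0.21 (0.02 percentile) and CDK inhibitors and quiescence genes -0.27 (0.1 percentile). Normexp background correction gave 139 higher and 78 lower genes, and under it the median of CDK inhibitors lay at the 14.5 percentile.

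The inhibitors alone, against DMSO, were accompanied by lower signal of ERK target genes, the read-out of the pathway that both drugs block. Of 31 measured genes of ERK pathway output 14 were at least 2-fold lower and 1, KLF6 (1.94), at least 2-fold higher, with a median of -0.94 at the 0 percentile. The immediate-early genes FOS and EGR1 were 7.13-fold and 6.38-fold lower, the ETS factors ETV1 and ETV4 6.82-fold and 5.91-fold lower, and the feedback phosphatase DUSP6 4.68-fold lower. Genes of G1/S and DNA replication had a median of -0.91, with 35 of 36 negative and 12 at least 2-fold lower, among them RRM2 (-1.32), FEN1 (-1.29) and ORC1 (-1.26). G2/M and mitosis genes had a median of -0.61, with 36 of 36 negative and AURKB (-1.23) at least 2-fold lower. Ribosome biogenesis genes had a median of -0.50, with 28 of 28 negative. Each of these medians lay at the 0 percentile.

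Genes of cell cycle exit were on the other side. CDK inhibitors and quiescence genes had a median of 0.51 (100 percentile), with 8 of 19 at least 2-fold higher, among them CDKN2B (2.48), CDKN1A (2.32), YPEL3 (1.97) and CDKN2C (1.42). The median of p53 targets was also 0.51 (100 percentile), with 9 of 25 at least 2-fold higher, among them TP53INP1 (3.57), GDF15 (2.67) and SPATA18 (2.40). Interferon response genes had a median of 0.57 (100 percentile), with 5 of 25 at least 2-fold higher, led by IFIT2 (15.3-fold) and IFIT1 (10.1-fold). HOX genes had a median of 0.29 (99.97 percentile, and 0.06 when scaled to the spike-in controls) with HOXB8 (1.31) and HOXB2 (1.01) higher. In the BCL2 family, which sets the threshold of apoptosis, the pro-apoptotic BMF (at least 2.68) and BBC3 (1.93) were higher and the anti-apoptotic MCL1 (-1.51) and BCL2A1 (-1.23) lower, around a median of -0.13 (29.2 percentile). YAP targets had a median of 0.22 (99.1 percentile). It was 0.07 at the 87.4 percentile with genes above background on both arrays only, 0.12 under normexp background correction, 0.42 with the mean over probes and -0.0038 when scaled to the spike-in controls. ANKRD1 was at least 23.9-fold higher and MYOF differed by 3.85, against DOCK5 (-1.17). PI3K and FOXO feedback genes had a median of 0.23 (98.0 percentile), at the 91.2 percentile with the mean over probes, at the 93.1 percentile with genes above background on both arrays only, and 0.0067 when scaled to the spike-in controls. Among them were PIK3IP1 (at least 3.37), INPP5D (at least 3.03) and PIK3R3 (2.34). For the 3 drugs against tretinoin the PI3K and FOXO feedback median was 0.08 (76.9 percentile), inside the central range.

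In all, 720 genes were at least 2-fold higher and 448 at least 2-fold lower with the inhibitors, of 17494 measured. KRT80 was 120-fold higher, CGB3 41.8-fold, ID2, a dominant-negative helix-loop-helix factor, 33.4-fold, SMAD3 30.7-fold, the caveolin CAV1 29.1-fold and the Notch and BMP target HEY1 28.7-fold. The DMSO signal of KRT80 (-4.66) lay near that array's floor of -4.76. It also enters the KRT80 values given above for tretinoin against DMSO and for the difference of the tretinoin effects. GPRC5A with DMSO (-4.53) and IFIT2 with tretinoin (-4.33, where the floor was -4.66) also lay near a floor. LMTK3 (4.45), CRIP2 (3.82), ACTG2 (3.78) and NOXA1 (3.74) followed, with bounds for the inhibitory SMAD gene SMAD6 (at least 39.0-fold) and for CAV3 (at least 3.72). USP22 (3.78) and RIC3 (-7.27) carry the defects named above. MAP1LC3C was 27.2-fold lower, MMP1 at least 28.4-fold lower, and STC1 (-4.29), GFPT2 (-4.17), LUCAT1 (-3.99), SEMA7A (-3.54), ACOX2 (-3.36), ANGPTL4 (-3.20), LNCOG (-3.06), PLAU (-2.71) and UPP1 (-2.57) were among the lowest, with bounds for TMEM156 (-3.30) and MMP3 (-2.38). Normexp background correction gave 320 higher and 194 lower genes. Scaling to the spike-in controls, which moved the median of all genes and of every list by -0.23, gave 470 and 915. It left CDK inhibitors and quiescence genes at 0.29, p53 targets at 0.28 and interferon response genes at 0.34.

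The inhibitor difference taken on the arrays with tretinoin shares no array with the one above. It had 848 genes at least 2-fold higher and 574 at least 2-fold lower of 17386, and 424 higher and 290 lower genes were found in both, where independent lists would share 32.5 and 13.96 of 16868. The Pearson r across genes was 0.76. ERK pathway output had a median of -0.74, G1/S genes -0.78 and G2/M genes -0.46, each at the 0 percentile, with DUSP6 (-3.19), EGR1 (-3.12) and FOS (-2.90) lower. Interferon response genes had a median of 0.61 (100 percentile) with 10 of 26 at least 2-fold higher, among them IFIT2 (38.8-fold), IFIT1 (20.2-fold) and IFIT3 (2.21). The retinoic acid response list, with a median of 0.00 (75.7 percentile) for the inhibitors against DMSO, had one of 1.29 (100 percentile, and 0.58 under normexp background correction) here, with 15 of 27 at least 2-fold higher. PTPRH (7.25), LMTK3 (5.65), STRA6 (5.47), S100A4 (5.36), PTGES (5.34), ENO3 (5.32), CLDN4 (4.57), CGB3 (4.38), NTN4 (4.32) and NOXA1 (4.11) were also among the highest, with bounds for S100P (6.28), SMAD6 (5.53), CYP26A1 (5.27) and ENTPD8 (5.24). GFPT2 (-3.69), PDE2A (-3.63), LNCOG (-3.62), RNF150 (-3.34) and AOX1 (-2.91) were among the lowest, with bounds for TMEM156 (-4.03), KRTAP2-3 (-3.40), MMP1 (-3.37) and MAGEB6 (-3.15). Normexp background correction gave 437 higher and 278 lower genes, and scaling to the spike-in controls gave 884 lower genes.

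The remaining lists are given for the inhibitors against DMSO and for tretinoin on top of them. Some are also given for the 3 drugs against tretinoin. Integrated stress response genes had medians of -0.26 (1.80 percentile) and -0.05 (36.2 percentile). The former lay inside the central range under 4 alternatives, at the 3.96 percentile under normexp background correction, 5.22 under quantile normalization, 2.66 with the mean over probes and 2.52 with genes above background on both arrays only. For the 3 drugs against tretinoin the list's median was -0.32 (0.915 percentile, but 2.835 under quantile normalization). Single members differed, with NUPR1 (3.20), ATF3 (2.69) and DDIT4 (1.87) higher with the inhibitors. Chaperones of the heat shock list had -0.43 (0.17 percentile, and -0.28 under quantile normalization) and -0.03 (46.4 percentile), with DNAJA1 (-0.86) and HSPA8 (-0.81) lowest. Their median for the 3 drugs against tretinoin was -0.39 (0.41 percentile). Cholesterol genes had a median of 0.16 with the inhibitors (99.6 percentile), 0.31 under quantile normalization, -0.07 when scaled to the spike-in controls, and at the 97.47 percentile of unmatched random lists. For the 3 drugs against tretinoin the cholesterol median was -0.08 (61.3 percentile), so the higher median was not repeated there. Autophagy and lysosome genes had medians of 0.19 (99.94 percentile, 0.39 under quantile normalization and -0.04 when scaled to the spike-in controls) and -0.11 (3.58 percentile), with the lysosomal proteases CTSA (1.81) and CTSB (1.27) higher with tretinoin. WNT targets had -0.31 (3.60 percentile, -0.15 under quantile normalization and -0.54 when scaled to the spike-in controls) and -0.08 (28.9 percentile). For the 3 drugs against tretinoin they had -0.52 (0.08 percentile, and -0.31 under normexp background correction). Receptor tyrosine kinases and their ligands had 0.14 (92.8 percentile, and -0.09 when scaled to the spike-in controls) and -0.04 (40.0 percentile), with FGFR3 at 1.41 with the inhibitors and HBEGF (-1.54) and HGF (-1.38) with tretinoin. For the 3 drugs against tretinoin this list had 0.35 (99.75 percentile, and 0.17 when scaled to the spike-in controls). Glycolysis and hypoxia genes had -0.19 (12.1 percentile, and 0.03 under quantile normalization) with the inhibitors, with HK2 at -1.85. For the 3 drugs against tretinoin they had -0.31 (0.80 percentile, but 2.58 under normexp background correction). Intestinal differentiation genes had -0.18 (14.9 percentile) and 0.16 (96.7 percentile), and epithelial-mesenchymal transition genes had 0.22 (97.3 percentile, but -0.03 under normexp background correction and -0.01 when scaled to the spike-in controls) with the inhibitors. Reference genes had medians between -0.09 and -0.01 in all 4 comparisons. Leukocyte markers, with 9 of 16 measured, had -0.07 (44.2 percentile) and -0.17 (13.9 percentile), and fibroblast and endothelial markers, with 4 of 14 measured, had 0.01 (55.3 percentile) and 0.07 (66.1 percentile). In the difference of the tretinoin effects leukocyte markers, with 7 measured, had -0.38 at the 1.54 percentile, outside the central range. Under normexp background correction that value was -0.0046 at the 4.725 percentile. Over all lists and the difference of the tretinoin effects, 60 of 130 medians lay outside the central 95% of random lists. Independent lists of random genes would give 6.5. The comparisons share arrays and the genes of a list can vary together, so 6.5 is not what error between cultures would give.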

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

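The patterns weighed here were noticed in the data. Of the tests, only that of array scaling was stated before its result was seen, and those of receptor levels, local defects and the inhibitor array were chosen afterwards.

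Retinoic acid response genes lay further above the matching control with the inhibitors than without, with 16 of 20 positive in the difference of the tretinoin effects, although SMAD7 (-1.64) and TGM2 (-1.24) were at least 2-fold lower. Array scaling that depends on signal is argued against, since the list's median stayed at the 100 percentile under normexp background correction (0.36) and quantile normalization (0.41). The other 3 scalings add 1 constant per array, which moves random lists alike and cannot alter a percentile. The number of positive members restates the pattern and does not bear on noise, so error of single arrays stays open. Higher receptor levels before tretinoin may contribute: the median inhibitor difference of 5 measured retinoid receptor genes was 0.19, with RARG at 0.75 and RARA at 0.38, too mixed to decide. The biological candidate, that blocked ERK signalling widens the response to retinoic acid, stays open beside receptor levels and slide position, which 1 array per group cannot tell apart from treatment.

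Median differences with tretinoin of YAP target genes were 0.18 without the inhibitors and -0.39 with them, which drew attention because the direction turned. The difference of both had a median of -0.62 at the 0 percentile of random lists, a ranking among genes only. Against error between cultures the difference was not tested. A candidate explanation is the reading of the inhibitor array alone, since it enters both the higher inhibitor difference and the lower tretinoin one. The former, with a median of 0.22, was itself unsteady, at -0.0038 when scaled to the spike-in controls. With the stricter filter on dim probes it was 0.07 at the 87.4 percentile. Comparing both tretinoin arrays, which leaves that array out, put the list's median at the 16.4 percentile, inside the range of random lists. A misread inhibitor array would give that. In the same comparison, however, 6 of 16 genes were positive and 10 negative, MYOF (3.095) was at least 2-fold higher, and 3 were at least 2-fold lower, among them CCN1 (-1.38) and CCN2 (-1.32). These members are mixed. The median of 0.18 without the inhibitors does not use the inhibitor array either, so a misread inhibitor array cannot account for that value. An inhibitor-specific higher level of these genes that tretinoin opposes would give the same percentile, so both stay open.

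RIC3 and USP22 were each high on 1 array only, and a local defect of that array is a likely source. Around RIC3 on the DMSO array, the background pixel SD was 18.9 times the array's median and 20 spots within 4 rows and columns were non-uniform. Around USP22 on the inhibitor array, these values were 8.72 and 4. The signals were 1735 for RIC3 against 2.35 to 2.65 on the other arrays, and 40776 for USP22 against 2509 to 2946. No biological explanation was tested.

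MAP1LC3C had tretinoin differences of -1.25 without the inhibitors and 2.12 with them, in opposite directions, and that difference was not tested either. The spike-in controls, RNA added in equal amounts and not used in the comparisons, lay above DMSO after scaling by a median of 0.081 with tretinoin, 0.23 with the inhibitors and 0.25 with the 3 drugs, over 8 spike-ins of which the single values ran from -0.18 to 0.38. Probes without a gene symbol, which the comparisons left out, included 105 at least 2-fold higher with tretinoin and 136 at least 2-fold higher with tretinoin on top of the inhibitors.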

How the results depend on the processing

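Scaling to the spike-in controls and leaving out spots near local defects were chosen after seeing the data, and the other alternatives were planned. Over all alternatives, 102 of 149 counts stayed within 1.5 times the reported count and 47 did not. The 102 include counts of named genes that had a value, which say nothing about their folds. They also include counts of lists outside the central range under scalings by a constant per array, which cannot alter a percentile. Under normexp background correction 12 of 14 counts moved, with all gene and overlap counts among them. Of 1170 list medians, 1082 moved by less than the standard error of the median over the list's genes and 84 by more. The 1082 include 130 with unmatched random lists, a setting that cannot move a median. A turned sign was counted apart only where the reported median lay outside the central range, which held for 4 of 540. Of the 630 others, 69 turned. Unmatched random lists, which cannot turn a median, make up 60 of the 540 and 70 of the 630. Under normexp background correction, 316 of 541 values of named genes moved by more than spot noise, with the mean over probes 78 and under quantile normalization 47. Of those at least 2-fold different, 0 turned. The Pearson r of both tretinoin differences lay between 0.36 and 0.39 over the 4 alternatives that could alter it. A constant per array cannot. Of the 60 list medians outside the central range, 7 fell inside it under normexp background correction, 3 each with the mean over probes and with the stricter filter, 2 each under quantile normalization and with unmatched lists, and 0 under the other settings. Among those other settings are 3 scalings by a constant per array, which cannot alter a percentile.

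Normexp background correction gave 100 higher and 10 lower genes for tretinoin, 219 and 51 for tretinoin on top of the inhibitors, 320 and 194 for the inhibitors, 437 and 278 for the inhibitors on top of tretinoin, and 139 and 78 for the difference of the tretinoin effects. The overlap was 32 higher genes and 1 lower gene. Its offset pulls low signals together, which lowers folds of dim genes by construction. Under it the median of WNT targets in the difference of the tretinoin effects was 0.0092 in place of -0.27, and the cause was not tested. The share of higher among called genes was 90.9% in place of 80.3% for tretinoin, and 81.1% in place of 69.7% on top of the inhibitors.

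Scaling to the spike-in controls moved the median of all genes by -0.23 for the inhibitors and by -0.17 for the inhibitors on top of tretinoin. The counts were then 470 higher and 915 lower for the former, and 884 lower for the latter. The share of higher genes was 33.9% in place of 61.6%, and 42.3% in place of 59.6%. The overlap had 8 lower genes. For the inhibitors, 3 medians outside the central range turned: cholesterol synthesis and uptake (-0.072), YAP targets (-0.0038) and autophagy and lysosome (-0.035). Whether the inhibitors lowered total mRNA per amount of RNA was not tested.

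Without a filter on dim probes, the counts in the same order of comparisons were 827 and 1010, 1080 and 885, 1370 and 1375, 1633 and 1295, and 1693 and 1411. These counts add probes at background, where signal over background limits the precision. With genes above background on both arrays only, tretinoin had 27 lower genes, because bounds drop out. A 1.5-fold threshold gave 564 and 442, 980 and 874, 1867 and 1768, 1929 and 1940, and 773 and 730. A 3-fold threshold gave 85 and 17, 171 and 31, 236 and 122, 329 and 229, and 89 and 36. No paired analysis was made, because each group has 1 array and an additive fit would take the difference of the tretinoin effects as its error.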

Other observations

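The genes in these paragraphs were chosen after their values were seen, and each value is a single difference without replicates. They were not a list fixed beforehand and were not ranked among random lists. With the inhibitors alone, ID1 was 7.88-fold higher, ID3 11.5-fold and ID2 33.4-fold, the receptor-regulated SMAD9 had a log2 difference of 1.92, and the inhibitory SMADs SMAD7 and SMAD6 were 8.57-fold and at least 39.0-fold higher. On the arrays with tretinoin, the inhibitor differences were 3.02 for ID1, 3.53 for ID3 and 3.29 for ID2. Tretinoin on top of the inhibitors was accompanied by lower ID2 (-1.79), SMAD7 (4.01-fold) and SMAD9 (-1.13), and by differences of 0.48 for ID1, 0.36 for SMAD6 and 0.10 for ID3.

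CAV1 and CAV2, which coat caveolae, had inhibitor differences of 4.87 and 2.96, the smooth muscle actin ACTG2 3.78, the transgelin TAGLN 2.11 and the myosin light chain MYL9 2.30. With tretinoin on top, ACTG2 was at -2.19, TAGLN at -2.47 and MYL9 at -0.83. ANGPTL4 was at -3.20 with the inhibitors and 3.85 with tretinoin on top, UPP1 at -2.57 and 2.83, and the urokinase PLAU at -2.71 and 1.52.

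Counting all genes, 90 were at least 2-fold higher with the inhibitors and at least 2-fold lower with tretinoin on top, where independent lists would share 7.13 of 16945, and 41 were opposite the other way, against 7.87. Both comparisons use the inhibitor array with opposite sign, so its errors alone produce opposition. Simulated spot noise gave a mean of 1.05 opposite genes in 20 simulations. That simulation covered only the 15877 genes measured on all 4 arrays, whereas the counts of 90 and 41 include bounds of dim genes. The simulated and observed counts were therefore not taken over like sets of genes. The covariance across genes was -0.0588 against -0.0135 from that noise, with a Pearson r of -0.27 against -0.50. Spot noise leaves out error of the whole culture or array, and part of the excess stays open to it. A further 45 genes were at least 2-fold higher in both, against 13.9.

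FAM229B was skipped by the naming rule because its probes disagreed. Of its 4 probes 3 were well above background on all arrays. A pair of them gave 7.04 and 7.07 with tretinoin and 7.02 for the latter with tretinoin on top of the inhibitors (128-fold for the former), while the third gave -0.01 and -0.41. Which transcript the pair detects was not analysed here.

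The histone genes H2BC26 and H2AC25 had tretinoin differences of 3.08 and 2.84 without the inhibitors and of 3.31 and 3.78 with them. Their inhibitor differences were -0.07 and 0.49 without tretinoin, and 0.16 and 1.43 with it. All 3 genes measured on all arrays that were at least 8-fold lower with tretinoin against DMSO had their spot in a local defect of the DMSO array.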
